A study of Mus musculus with 10 samples.

How the data were processed

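RNA bound to EGFP-tagged ribosomes was measured in 10 libraries of mouse medial habenula, 5 from the left and 5 from the right side, all immunopurified. Per the labels' protocols, the sides were dissected and homogenised separately, tagged polysomes were captured with anti-EGFP antibodies on magnetic beads, and RNA was purified from the pull-down. The labels name the side, the replicate number, the sequencing lane and the index of each library. The titles also carry a number in brackets, without saying what it stands for. By that number, replicate 1 of both sides lies apart from a consecutive run that holds all other libraries. Groups were taken from the title of each sample. No unpurified input library was used here, so enrichment over the tissue was not measured.

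The deposited values are raw counts of reads per gene, 1 file per library, not normalised. Per the submitters' processing notes, STAR 2.0.0e, HTSeq and the build mm10 were used; the gene annotation, the strand setting and the filters of the counting are not given in the sources used here. Each file has 32537 rows, of which 6 name no gene (5 summary lines of the counter and a row named unknown with 0 to 4 reads). These were left out of library sizes and tests. Reads outside genes were 13.6% to 18.9% of uniquely aligned reads and reads in overlapping genes 2.25% to 2.81%, and further alignments that were not unique were not counted by the authors. Of 32531 gene rows, 23155 names matched the GENCODE M21 annotation of GRCm38 (mm10), which gave coordinates for 80 of the 84 genes chosen for the text; AK017243, AK076318, Gm10536 and Gm17296 had no match. Reads that HTSeq finds ambiguous or not uniquely aligned are lost to genes that overlap others or have near-identical copies. Besides those named as uncertain in the report, Nwd2, Lrrc55, Xist, Slc1a2, Rora and Pcdh10 share exonic bases with a gene of the other strand in that annotation, so their counts are uncertain to that extent.

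Gene counts summed to between 42488448 and 67942836 reads per library. At that depth counting noise is small against the spread between libraries for most genes named. The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr by side with a minimum count of 10, robust fit, side as the only term, two-sided), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Intervals are 95% intervals of the log2 fold change from that fit, with the standard error taken from the F statistic. CPM values use TMM-scaled library sizes, and log2 CPM has a prior count of 2.

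Gene lists were tested with camera of limma 3.58.1 at an inter-gene correlation preset to 0.01, with an estimated correlation beside it, and with fry. The mean log2 CPM of each list per library was compared by an exact permutation test over 252 assignments. Of 31 lists, 30 had at least 3 tested members; the list of genes of the mitochondrial genome was not analysed here. The lists, the groups, the main tests and the rule for naming genes were fixed before the data were examined. The rule took genes past the threshold with a mean of at least 1 CPM, and, where fewer than 10 passed, the 8 genes per direction with the smallest unadjusted p, the 2 most abundant tested members of each list without a call, and a set of habenular and sex-linked genes. Genes outside it are marked in the text. A few genes are not reported here.

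The glial score of a library is its mean log2 CPM of the tested members of the astrocyte, oligodendrocyte, microglia and endothelium lists. Alternatives set in advance were other normalisations, other filters for low counts, DESeq2 1.42.0 (Wald test), limma-voom with sample weights, the glial score as a covariate, the replicate number as a block, a threshold of 0.10, and leaving out each library. Alternatives added after seeing the data were replicates 1 and 5 of each side summed, replicates 2 to 4 alone, replicates 1 and 5 alone, and the estimated correlation together with the block or the covariate. Similarity of libraries was measured by chi-square tests of counts, using genes with 20 to 100 and with 100 to 500 reads in a pair of libraries.

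The fit was tested on simulated data: 5 sets of counts for 16058 genes, with 200 genes changed in each. For 2-fold changes the fit by side alone recovered 46.6% (43% to 53% over the sets) and for 4-fold changes 85.2% (82% to 88%), with 0 false calls. With the glial score as a covariate it recovered 96.4% and 100%, with 52 false calls over the 5 sets. The counts were drawn from a fit with the glial score as its term, so recovery with that covariate is a best case. All libraries were drawn as independent, and only genes with a mean of at least 1 CPM were changed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.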

Results

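The medial habenula is a paired epithalamic nucleus whose ventral neurons release acetylcholine and glutamate and project to the interpeduncular nucleus. Its left and right sides were dissected separately from adult mice of the Chat-TRAP line DW167, a transgenic line that places an EGFP tag on the ribosomal protein Rpl10a in neurons expressing choline acetyltransferase. Tagged polysomes were pulled down with antibodies to EGFP (translating ribosome affinity purification, TRAP) and the bound RNA was sequenced. There were 10 libraries, 5 from the left and 5 from the right, all of them pull-downs. Total gene counts were 59310593, 63122001, 59177684, 65664809 and 55425795 reads for left replicates 1 to 5. They were 67132334, 65163980, 66016203, 42488448 and 67942836 reads for right replicates 1 to 5. Between 18427 and 20948 genes had at least 1 read. The labels do not say that the libraries of a side came from separate animals, so no p-value below can be taken to measure the spread between animals. The spread between these libraries may be partly technical. Errors are SD over 5 libraries per side unless another error is named, levels are normalised CPM (counts scaled to 1e6 reads per library), and log2 fold changes are left minus right.

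The pull-downs carried the transcripts that mark medial habenular neurons at high levels on both sides. Nwd2, an abundant habenular transcript, stood at 2388 ± 488 CPM on the left and 2307 ± 496 CPM on the right. Lrrc55, an auxiliary subunit of BK potassium channels, stood at 1731 ± 484 and 1703 ± 655 CPM. The most abundant tested transcript of a receptor was Gabbr1, a GABA-B receptor subunit, at 4016 ± 1029 CPM on the left and 3908 ± 1177 CPM on the right. Transcripts of the Y chromosome were present in all 10 libraries. Ddx3y stood at 72.8 ± 13.4 CPM on the left and 76.4 ± 11.8 CPM on the right. Xist, the RNA of the inactive X chromosome, stood at 0.156 ± 0.112 and 0.131 ± 0.128 CPM.

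The amount of RNA from other cell types differed far more between libraries of the same side than between the sides. The mean log2 CPM of 15 astrocyte markers lay between 1.47 and 1.66 in replicates 1 and 5 of both sides and between 3.50 and 5.32 in the other 6 libraries, a 14.3-fold range. Mbp, the myelin basic protein of oligodendrocytes, ranged from 17.9 CPM in right replicate 5 to 589 CPM in right replicate 3, and Slc1a2, the main astrocytic glutamate transporter, from 33.6 to 1074 CPM. Rora, a nuclear receptor abundant in thalamic neurons, ranged from 138.5 to 823.8 CPM. Gpr151, an orphan receptor of habenular axons, ran the other way and stood at 543 to 562 CPM in replicates 1 and 5 and at 209 to 382 CPM in the other 6 libraries. The first principal component of log2 CPM held 79.4% of the variance and separated replicates 1 and 5 of both sides from left replicates 2 to 4 and right replicates 3 and 4, with right replicate 2 between them. The second held 4.96%.

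**Figure D1:**
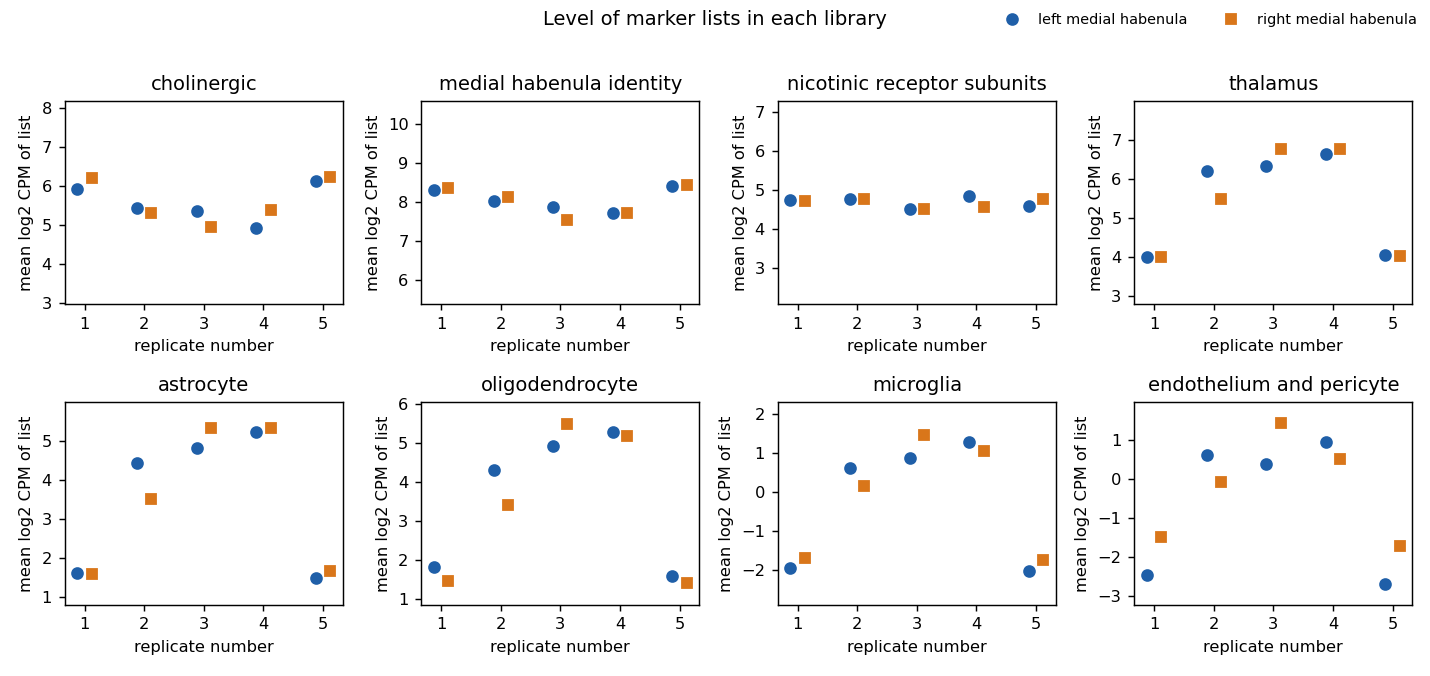
Each panel gives the mean log2 CPM of a marker list (vertical axis) by replicate number (horizontal axis), with circles for left and squares for right libraries, and all panels span the same number of log2 units. Astrocyte levels ranged from 1.47 to 5.32 and nicotinic receptor subunits only from 4.51 to 4.84, with replicates 1 and 5 of both sides lowest for glial markers.

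The comparison of the sides asked which transcripts of these cholinergic-line neurons differ between the left and right medial habenula. Genes of acetylcholine synthesis and transport had similar levels on both sides. Chat, which makes acetylcholine, stood at 127 ± 43.3 CPM on the left and 137 ± 54.2 CPM on the right (log2 fold change -0.11, 95% CI -0.78 to 0.57). Slc18a3, the vesicular acetylcholine transporter, stood at 399 ± 160 and 427 ± 154 CPM (-0.10, -0.85 to 0.66). Slc5a7, the choline transporter, stood at 228 ± 45.1 and 214 ± 65.1 CPM (0.10, -0.40 to 0.59). Of the 6 measured cholinergic genes 1 had a higher mean on the left. The level of the list, its mean log2 CPM, was 5.57 ± 0.48 on the left and 5.62 ± 0.58 on the right. It was lowest in left replicate 4, at 4.92, and highest in right replicate 5, at 6.24.

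No gene passed the threshold between the sides. The edgeR quasi-likelihood test gave 0 of 16250 genes with an adjusted p under 0.05 (0 higher on the left, 0 higher on the right), and the smallest adjusted p was 1. At an unadjusted p under 0.05 there were 90 genes (41 higher on the left, 49 on the right), where chance alone gives 812. DESeq2 gave 0 genes with 141 at an unadjusted p under 0.05, also below the count from chance. In limma-voom with sample weights 0 genes passed (smallest adjusted p = 0.282), but 2409 had an unadjusted p under 0.05, above the 812 from chance. All 8962 genes with a mean of at least 10 CPM had a fitted log2 fold change between -0.5 and 0.5, with a median size of 0.05. For 8216 of them the 95% interval lay between -1 and 1. With the glial score of each library as a covariate the edgeR count was again 0, with 510 genes at an unadjusted p under 0.05. The median half-width of the intervals of abundant genes was then 0.20 in place of 0.38. In data simulated from the means, library sizes and spread of 16058 genes, the test without a covariate recovered 46.6% of 2-fold and 85.2% of 4-fold changes. The simulation drew all libraries as independent, which replicates 1 and 5 of a side may not be. With replicates 1 and 5 alone, a choice made after the data were seen, the same test called 1992 genes (893 higher on the left, 1099 on the right). The 2 libraries of a side in that test may come from the same RNA, so its count does not measure the spread between animals. Lanes 4, 5, 1 and 2 each held 1 left and 1 right library, those of replicates 2 to 5. With these lanes as a block, edgeR called 0 of 16517 genes with 133 at an unadjusted p under 0.05. Replicate 1 was run in lane 7 on the left and lane 3 on the right and is not in that fit.

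**Figure D2:**
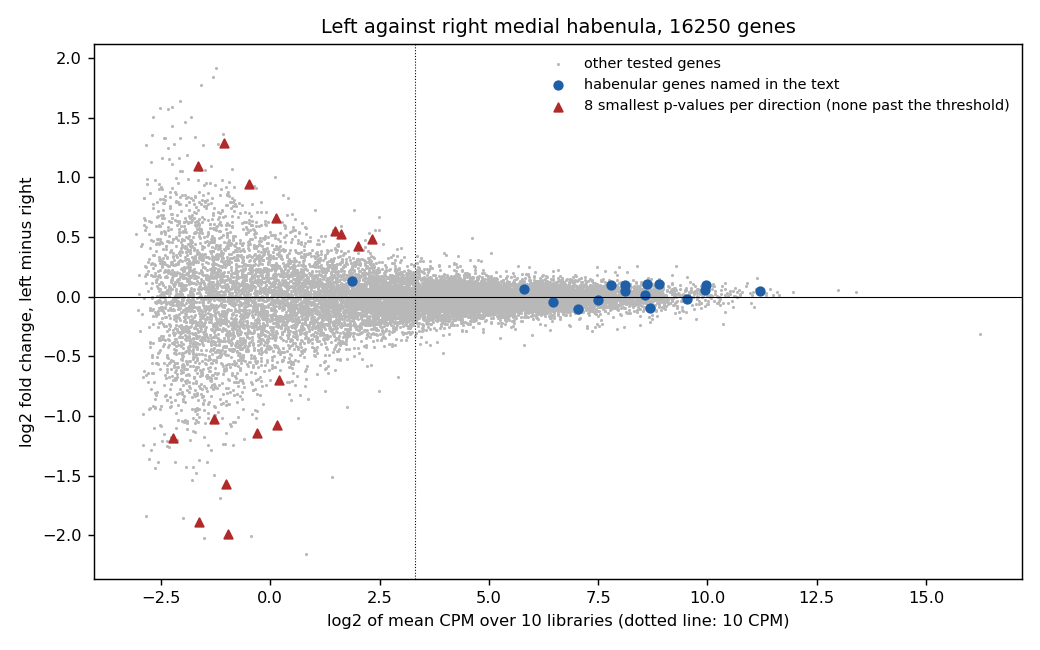
Each point is 1 of 16250 tested genes, with its mean CPM on a log2 scale on the horizontal axis and its log2 fold change, left minus right, on the vertical axis. All 8962 genes right of the dotted line at 10 CPM lie between -0.5 and 0.5, habenular genes (blue circles) among them except Chrna5, while the 8 smallest p-values per direction (red triangles) lie left of it.

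Nicotinic receptor subunits had the smallest spread of their mean level among the habenular lists, while single subunits varied more. Chrna3 and Chrnb4, the subunits of the α3β4 receptor typical of the medial habenula, stood at 1039 ± 137 and 1010 ± 169 CPM on the left and at 973 ± 284 and 971 ± 304 CPM on the right (log2 fold changes 0.09 and 0.06). Chrnb3 stood at 288.5 ± 66.1 and 270.0 ± 84.5 CPM (0.10, 95% CI -0.44 to 0.63) and Chrna5, an accessory subunit, at only 3.85 ± 1.69 and 3.52 ± 1.10 CPM (0.13, -0.59 to 0.85). Chrna5, Chrna3 and Chrnb4 form a cluster on chromosome 9 of GRCm38 (mm10). Chrna5 lies on the plus strand from 54980880 to 55007779, Chrna3 on the minus strand from 55010111 to 55026562 and Chrnb4 on the minus strand from 55028154 to 55048779. The genes do not overlap one another. The level of the list of 10 measured subunits was 4.69 ± 0.14 on the left and 4.67 ± 0.12 on the right and ranged 1.25-fold over the 10 libraries. Chrna3 ranged from 629.7 to 1262 CPM and Chrnb4 from 633 to 1248 CPM. Of its members 8 had a higher mean on the left. Slc18a3 (chromosome 14, 32462438 to 32464850, minus strand) is a gene of 1 exon inside Chat (32408203 to 32465989, minus strand), and the annotation gives them no shared exonic base.

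Transcription factors, transmitter and signalling genes of the medial habenula also showed no difference beyond the spread between libraries. Pou4f1, the transcription factor that specifies habenular neurons, stood at 282 ± 88.8 CPM on the left and 272.5 ± 83.6 CPM on the right (log2 fold change 0.05, 95% CI -0.55 to 0.65). Tac2, the neurokinin B precursor of ventral neurons, stood at 739 ± 295 and 749.6 ± 347 CPM (-0.02, -0.87 to 0.83). Gpr151 stood at 406 ± 146 and 377 ± 165 CPM (0.11, -0.66 to 0.87). The vesicular glutamate transporters Slc17a6 and Slc17a7 stood at 383 ± 67.5 and 489 ± 92.4 CPM on the left and at 379 ± 57.9 and 455 ± 115 CPM on the right. The level of the 20 identity genes was 8.07 ± 0.29 on the left and 8.03 ± 0.39 on the right, with 10 members higher on each side. Among markers of the dorsal, substance P part of the nucleus, Tac1, the substance P precursor, stood at 57.1 ± 25.2 and 54.7 ± 26.1 CPM. Adcyap1, the precursor of PACAP, stood at 66.3 ± 26.4 and 64.05 ± 26.8 CPM. The 6 genes of the list had a level of 3.92 ± 0.29 on the left and 3.95 ± 0.29 on the right. Tac2, Gpr151, Tac1 and Adcyap1 were all at their highest in replicates 1 and 5 of both sides, the libraries with the least glial RNA.

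**Figure D3:**
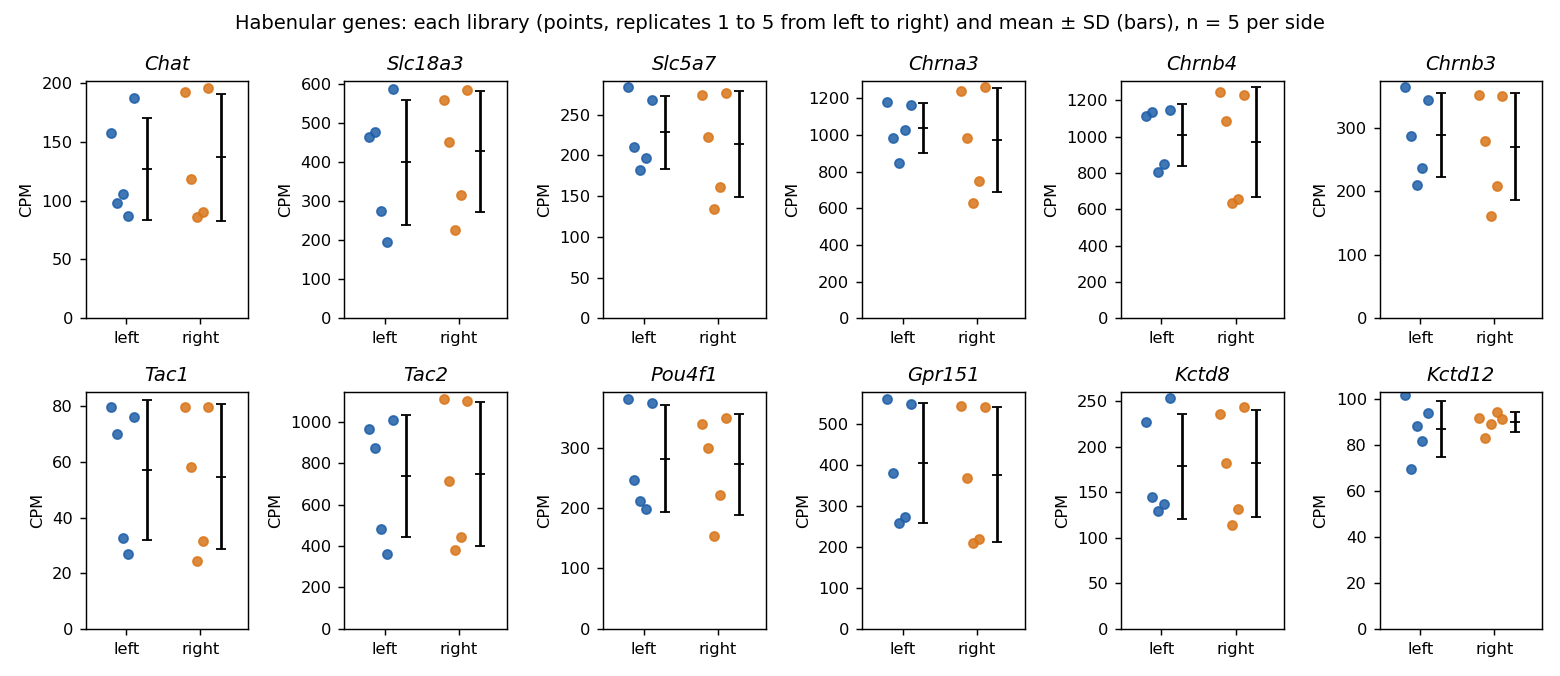
Points give the CPM (vertical axis, linear and from 0) of 12 habenular genes in each left and right library, in the order of replicates 1 to 5, and bars the mean with SD over 5 libraries per side. The spread within a side exceeds the difference between the sides for each gene, as for Chat at 127 ± 43.3 CPM on the left and 137 ± 54.2 CPM on the right.

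Genes known for left-right differences elsewhere were examined as lists. The zebrafish habenula has unequal sides, and 14 mouse counterparts of genes studied there were measured, of which 5 had a higher mean on the left. Kctd12 and Kctd8, auxiliary subunits of GABA-B receptors whose fish relatives are unequally expressed, stood at 87.0 ± 12.2 and 178 ± 57.6 CPM on the left and at 90.0 ± 4.32 and 181.5 ± 58.8 CPM on the right. Their log2 fold changes were -0.05 (95% CI -0.29 to 0.19) and -0.03 (-0.63 to 0.58). Tcf7l2, a Wnt effector required for habenular asymmetry in fish, stood at 1186 ± 42.1 and 1227 ± 58.3 CPM (-0.05, -0.23 to 0.13). Nrp2, a semaphorin receptor, stood at 462 ± 96.4 and 460.5 ± 128 CPM. The largest log2 fold change in that list was 0.18, and its level was 5.64 ± 0.15 on the left and 5.66 ± 0.12 on the right. Of 18 genes of the embryonic Nodal pathway and its ciliary upstream steps, 10 had enough reads for the test and 5 of these had a higher mean on the left. Gdf1 stood at 27.3 ± 4.42 and 28.2 ± 3.60 CPM. The level of the list was 2.37 ± 0.45 on the left and 2.35 ± 0.49 on the right. Gdf1 shares all of its exonic bases with Cers1, and Kctd12 (chromosome 14, 102976581 to 102982637) overlaps an antisense gene, so reads of these could not be assigned to 1 gene with certainty. The strand setting of the counting is not given in the sources used here.

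Lists of peptides, receptors, ion channels and axon guidance genes had a wider spread of their mean level than the nicotinic list, each with its lowest level in left replicate 1 or 5. Among 25 measured neuropeptide genes 11 had a higher mean on the left. Chgb, a granin of dense-core vesicles, stood at 375 ± 108 CPM on the left and 359.9 ± 79.2 CPM on the right. Of 27 peptide and opioid receptors 15 had a higher mean on the left. Tacr1, the substance P receptor, stood at 139 ± 22.5 and 140.1 ± 41.4 CPM. Among 32 monoamine and muscarinic receptors 15 had a log2 fold change above 0. Htr5b stood at 270.5 ± 24.2 and 254 ± 74.5 CPM and Htr5a at 117.5 ± 8.16 and 109.5 ± 23.3 CPM. The lists of GABA and glycine receptors (11 of 20 higher on the left), glutamate receptors (13 of 25) and axon guidance genes (26 of 43) had levels of 4.18 ± 1.28, 4.74 ± 0.86 and 4.48 ± 0.62 on the left and of 4.25 ± 1.18, 4.71 ± 0.77 and 4.48 ± 0.53 on the right. Of 39 channels of pacemaking and excitability 31 had a higher mean on the left with a median log2 fold change of 0.05, and the level of that list was 5.86 ± 0.74 on the left and 5.82 ± 0.62 on the right. Cacna1e, an R-type calcium channel, stood at 929 ± 28.7 and 896 ± 94.5 CPM. Levels of neuropeptides, peptide receptors and monoamine receptors were 2.69 ± 0.55, 1.55 ± 1.04 and 1.27 ± 0.89 on the left and 2.85 ± 0.35, 1.60 ± 0.91 and 1.34 ± 0.84 on the right. Immediate early genes (9 of 19 higher on the left) had levels of 2.37 ± 0.69 and 2.36 ± 0.71 and clock genes (6 of 18) of 5.24 ± 0.30 and 5.27 ± 0.31. Arc stood at 31.6 ± 5.39 and 30.5 ± 3.26 CPM and Clock at 315 ± 46.5 and 314 ± 30.8 CPM.

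Markers of neighbouring tissue and of other cells gave the composition of the samples by side. Astrocyte, oligodendrocyte, oligodendrocyte precursor and microglia markers had levels of 3.51 ± 1.82, 3.59 ± 1.75, 2.55 ± 1.74 and -0.23 ± 1.61 on the left and of 3.47 ± 1.85, 3.40 ± 1.95, 2.51 ± 1.54 and -0.14 ± 1.497 on the right. Endothelial and pericyte markers stood at -0.66 ± 1.78 on the left and -0.28 ± 1.33 on the right, with 12 of 14 members at a higher mean on the right. The 3 measured blood genes stood at -1.49 ± 0.90 and -1.67 ± 1.21. Thalamic, lateral habenular and hippocampal markers stood at 5.45 ± 1.30, 4.27 ± 1.09 and 3.18 ± 0.60 on the left and at 5.42 ± 1.38, 4.28 ± 1.01 and 3.06 ± 0.58 on the right. Markers of GABAergic neurons stood at 1.496 ± 1.13 and 1.20 ± 1.21 and those of choroid plexus and ependyma at -0.00085 ± 0.43 and -0.32 ± 0.66. Markers of the pineal gland, which lies beside the habenula, stood at 0.47 ± 0.36 and 0.9995 ± 0.81. The 5 measured sex-linked genes had levels of 3.35 ± 0.24 and 3.30 ± 0.17. An exact two-sided permutation test over all assignments of the libraries to sides gave 0 of 30 lists past the threshold. The smallest exact permutation p was 0.238, for the pineal list (adjusted p = 0.992), and the smallest p possible was 0.00794. A single list at that smallest p would not pass after adjustment over 30 lists, so this test could not call 1 list by itself.

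As sets against the other genes, 4 of the 30 lists passed the threshold in limma's camera test with an inter-gene correlation preset to 0.01. Ribosomal protein genes had 67 of 77 log2 fold changes below 0 and a median log2 fold change of -0.10. Nuclear genes of oxidative phosphorylation had 73 of 81 below 0 and a median of -0.08. Both were called higher on the right (adjusted p = 0.0421 for each, adjusted p = 0.974 for each with an estimated correlation). The estimated correlations were 0.871 and 0.731, far above the preset 0.01, so the preset test treats members as more independent than they were. The most abundant member of each ran the other way. Rpl4 stood at 424 ± 56.4 CPM on the left and 416 ± 55.4 CPM on the right. Atp5b, the catalytic β subunit of ATP synthase, stood at 3224 ± 408 and 3190 ± 326 CPM. The next most abundant followed their lists, with Rps3 at 181 ± 55.0 and 189.5 ± 46.9 CPM and Atp5a1 at 961 ± 236.5 and 1015 ± 167 CPM. Both families have processed pseudogenes that can share reads with them. Levels were 3.47 ± 0.62 and 3.59 ± 0.54 for the ribosomal proteins and 6.10 ± 0.60 and 6.21 ± 0.49 for oxidative phosphorylation. Both were at their highest in replicates 1 and 5. The pineal list was called higher on the right (median log2 fold change -0.53, adjusted p = 0.0464, adjusted p = 0.690 with an estimated correlation of -0.0644). Chosen after their values were seen, its members Sag, Tph1 and Rbp3 stood at 0.136 ± 0.137, 0.292 ± 0.318 and 0.653 ± 0.116 CPM on the left and at 0.565 ± 0.613, 1.19 ± 1.80 and 1.10 ± 0.802 CPM on the right. Chrna3, another of its 6 measured members, is a habenular gene. The rest of the 12 pineal genes were not tested, among them Aanat, Asmt and Crx with at most 5, 1 and 7 reads in any library. The level of the pineal list was 1.47 and 2.19 in right replicates 3 and 4. It was 0.31 to 0.56 in the other right libraries and at most 0.81 on the left. The choroid plexus and ependyma list was called higher on the left (adjusted p = 0.0421, adjusted p = 0.974 with an estimated correlation of 0.214). Yet 6 of its 12 members lay on each side and its median was -0.01. With an estimated correlation 0 lists passed (smallest adjusted p = 0.690), and fry, which asks whether a list moves 1 way on balance, gave an unadjusted smallest p of 0.0678 in limma.

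Which lists were called also changed with the fit. With median-of-ratios size factors the pineal list was not called. With the replicate number as a block, or with the glial score as a covariate, the pineal and choroid plexus lists were no longer called and the oligodendrocyte list was called higher on the left. With the covariate the endothelium list was called higher on the right and the channel list higher on the left. The oligodendrocyte and endothelium lists are part of the glial score. With that score held fixed, opposite directions of these lists are partly built into the fit. The ribosomal and oxidative phosphorylation lists were called higher on the right in both fits. With an estimated correlation 0 lists were called in either fit. The number of lists called in the camera test depended on single libraries. It was 0 without left replicate 3 and 1 without left replicate 4, right replicate 1 or right replicate 5. In each of the latter the list called was endothelium, higher on the right, so the 4 lists called over all libraries each lost their call when any 1 of these 4 libraries was left out. Without left replicate 2 only the ribosomal list of these 4 kept its call, and the endothelium and neuropeptide lists were called higher on the right. The number of lists called was 3 without left replicate 2 or right replicate 2, 4 without right replicate 4, 8 without right replicate 3 and 9 without left replicate 1 or left replicate 5. Without right replicate 2 the choroid plexus list lost its call. Without right replicate 4 the pineal list lost its call and the oligodendrocyte list was called higher on the left. In 11 of the 30 lists the median, the difference of levels and the direction of the camera test were not all of the same sign: dorsal habenula, lateral habenula, thalamus, choroid plexus and ependyma, astrocyte, blood, immediate early, peptide receptors, monoamine receptors, GABA and glycine receptors and axon guidance. None of the 578 list genes tested passed in edgeR over all genes. In addition, 0 lists had a gene past the threshold when adjusted over the list alone (smallest adjusted p = 0.319). At an unadjusted p under 0.05 there were 2 list genes, named after their values were seen. Chrm4, a muscarinic receptor, stood at 0.211 ± 0.162 CPM on the left and 0.694 ± 0.443 CPM on the right. Cldn2, a tight junction gene of the choroid plexus, stood at 0.518 ± 0.295 and 0.148 ± 0.173 CPM.

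The genes with the smallest unadjusted p were of low abundance, and 9 of the 16 taken by the rule had a mean under 1 CPM. On the right side the smallest p belonged to Samd3 (chromosome 10, 26229707 to 26272172), with 0.206 ± 0.0775 CPM on the left and 0.824 ± 0.454 CPM on the right (log2 fold change -1.99, edgeR unadjusted p = 0.00146, adjusted p = 1). Isx, an intestinal homeobox gene, followed with 0.137 ± 0.0746 and 0.509 ± 0.238 CPM, then AK076318, Tnnc1, Serpina3g, Morn3, Fut4 and AK017243. On the left side it belonged to Sh2d6 (chromosome 6, 72513641 to 72521707), with 0.686 ± 0.199 and 0.279 ± 0.0826 CPM (log2 fold change 1.29, edgeR adjusted p = 1). It was followed by Oscar, Arsk, Zgrf1, Fam161a, Gm10536, Gm17296 and Tnfrsf22. Fam161a, a ciliary gene, was the most abundant of these at 5.85 ± 0.882 and 4.20 ± 0.600 CPM. Serpina3g and Tnfrsf22 belong to families of near-identical genes and Morn3 and Zgrf1 overlap genes of the other strand, so their counts are uncertain. Samd3 and Isx were highest in right replicates 1 and 5, which may not be separate samples. Samd3 stood at 1.34 and 1.28 CPM there and at 0.398 to 0.654 CPM in the other right libraries. Isx stood at 0.852 and 0.641 CPM there and at 0.249 to 0.416 CPM in the others of that side. Over all genes 33 (0.203%) had no overlap between the 5 left and 5 right values, where chance gives 0.794%. That chance value assumes interchangeable libraries. Replicates 1 and 5 of both sides differed from the rest, which makes the values of the sides overlap. A share below 0.794% therefore does not tell against a difference between the sides.

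Replicates 1 and 5 of the same side resembled each other more than any other pair of libraries. Over genes with 100 to 500 reads in the pair, the coefficient of variation beyond counting noise was 5.04% between right replicates 1 and 5 and 9.52% between left replicates 1 and 5. It was 16.2% to 19.3% between a left and a right library of those numbers and 21.3% to 66.4% for other pairs of the same side. A chi-square test found variation beyond counting noise within both pairs (2305 genes and p = 8.77e-24 on the right, 2335 genes and p = 1.09e-201 on the left). Library preparations of 1 RNA can also exceed counting noise, so the test does not tell whether the pairs are separate samples, and they were counted by their labels. Summed as 1 library per side, they left 0 genes past the threshold in edgeR with 23 at an unadjusted p under 0.05.

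**Figure D4:**
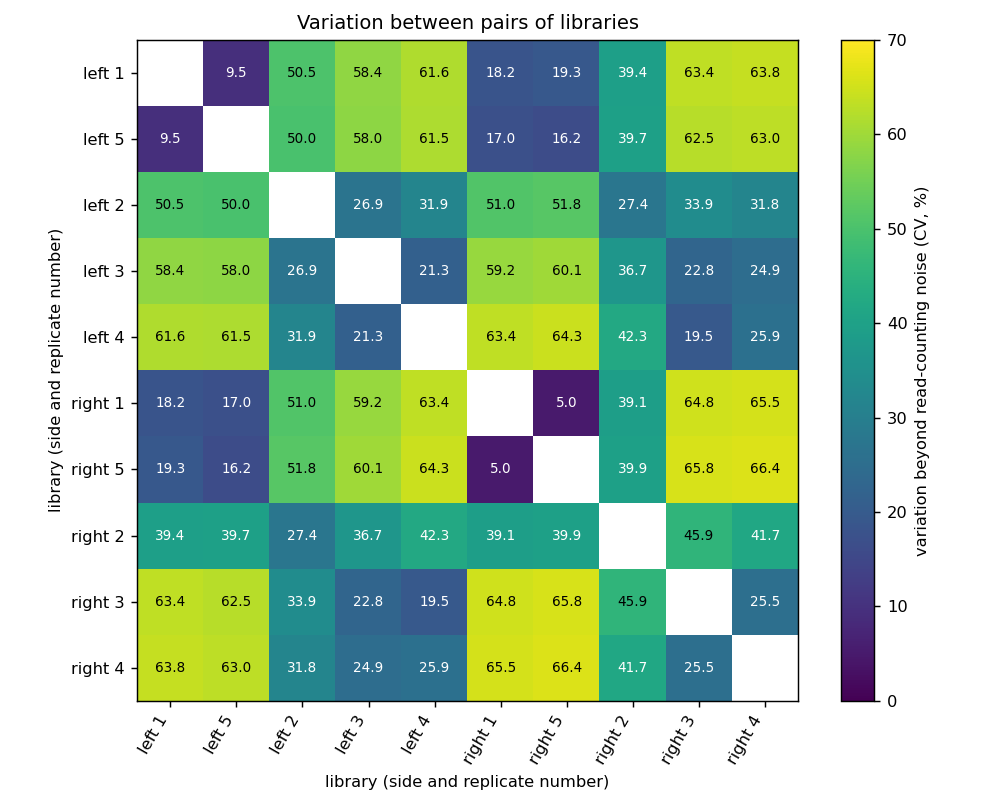
Each coloured cell gives the coefficient of variation beyond read-counting noise, in percent, for a pair of the 10 libraries named on both axes by side and replicate number. The pairs of replicates 1 and 5 within a side have the lowest values, 5.04% on the right and 9.52% on the left, and the highest value is 66.4%.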

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

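The test for a library far from the others of its side was set before the data were examined, and no explanation was tested here. It was applied to 234 groups of 5 values; chance alone gives 5% of them, or 11.7, and 8 were found.

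The sum of gene reads of right replicate 4 was 42.5 (in units of 1e6 reads), with 65.2 in the nearest of the other right libraries. For genes near 1 CPM or below, Tnnc1 stood at 0.119 CPM in left replicate 3 (nearest 0.263) and at 1.49 CPM in right replicate 4 (nearest 0.676), and Morn3 at 0.895 CPM in right replicate 4 (nearest 0.535). Arsk, a sulfatase gene, stood at 3.67 CPM in right replicate 2 (nearest 3.42). Among abundant genes, Sema5a, an axon guidance ligand, stood at 565 CPM in right replicate 2 (nearest 435) and Atp5b at 2620 CPM in the same library (nearest 3230). The Y-linked gene Uty stood at 25.3 CPM in left replicate 4 (nearest 21.2).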

How the results depend on the processing

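Settings with replicates 1 and 5 summed or alone, replicates 2 to 4 alone, and an estimated correlation with a block or covariate were chosen after the data were seen. The count of genes between the sides was 0 in 26 of 27 settings, with 23 to 2409 genes at an unadjusted p under 0.05 in edgeR, DESeq2 or limma-voom (50 to 149 when leaving out 1 library), and 1992 with replicates 1 and 5 alone. Replicate numbers were not taken as pairs: deviations of same-numbered libraries correlated at 0.86, 0.10, 0.81, 0.71 and 0.87 for numbers 1 to 5 (0.0962 for number 2), and 6 of 10 libraries correlated best with their own number. The fit with the replicate number as a block called 0 genes (297 at an unadjusted p under 0.05) and, without replicate 1, where the block is also the lane, 0 (133). Called lists numbered 4 in the main test, 0 with an estimated correlation (also with the block or the covariate), 3 with the block, 5 with the glial covariate, 0 to 9 when leaving out 1 library and 8 with replicates 1 and 5 alone; the cause was not tested. No list level passed when leaving out 1 library or with sign flips within numbers (smallest p possible 0.0625), the only settings run for levels. Of 84 named genes 66 had the other sign in at least 1 setting (354 of 2254 values), none of these fold changes having passed with all libraries. With replicates 1 and 5 alone 19 named genes passed. Only Pcdh10 at -0.31 and Kcnma1 at -0.13 had the other sign over all libraries. The others kept their sign, among them Tac2 at -0.16 and most of the 16 genes with the smallest unadjusted p in the main test. Those libraries are also part of the main test, so this is no separate support. The cause was not tested. Depth did not limit abundant genes; genes under 1 CPM rest on few reads.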

Other observations

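The comparison with other splits of the libraries was set in advance; the count over balanced splits and the tests of replicates 1 and 5, of carried-over RNA and of the spread of the fit were chosen after the results were seen, and the genes of the next paragraphs were named after their values were seen.

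Among the most abundant transcripts, Map1b, a microtubule-associated protein, stood at 10970 ± 4892 CPM on the left and 10670 ± 4631 CPM on the right, and Snap25, a SNARE protein of synaptic vesicle release, at 8349 ± 955 and 8010 ± 735 CPM (SD over 5 libraries per side). Vamp2, Cplx1 and Gnao1 stood at 2028 ± 322, 1810 ± 156 and 2898 ± 117 CPM on the left and at 1982 ± 357, 1757 ± 424 and 2862 ± 338 CPM on the right. None of these passed the edgeR test between the sides. Rn45s, the precursor of ribosomal RNA, was the most abundant row and stood at 8910 CPM of all gene reads in left replicate 4 and at 62700 to 102000 CPM in the other 9 libraries.

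Hcrt, the orexin precursor of hypothalamic neurons, had 226 reads in left replicate 3 and at most 19 in any other library. Oxt and Avp, the oxytocin and vasopressin precursors, had 102 and 62 reads in right replicate 3 and at most 25 and 23 elsewhere. Nodal, an embryonic left-right signal, had 6 to 51 reads per library (log2 fold change 0.14, 95% CI -0.96 to 1.23).

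For the count of 0 genes between the sides, all 100 of 100 splits of the 10 libraries into 5 and 5 gave as many, which no split can fail to do, so this says nothing about chance. The highest other count was 9536. Of these splits 5 put replicates 1 and 5 of both sides together, and 3 of the 5 gave 3597, 8252 and 9536 genes while all other splits gave 0. This points to a structure of the samples by replicate and cannot show whether there is also one by side. For the 4 lists called with a preset correlation chance cannot be excluded either, since 63 of 100 splits gave at least 4, with 21 as the highest other count. Among the 48 splits, the real one included, that put 2 of the 4 libraries of replicates 1 and 5 on each side, 11 gave at least 4, again with the real one included, and the highest other count was 11.

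The 1992 genes called with replicates 1 and 5 alone include Tbr1 (log2 fold change -2.61), Meis2 (-2.39) and Gad2 (-0.89), higher on the right, and Rragd (0.63), higher on the left. A left-right difference carried by the neurons of every replicate needs slopes near 1 where both sides hold similar amounts of other RNA. The test below cannot decide on it. Glial scores differed between the sides in replicates 2 and 3, and replicate numbers were not taken as pairs. Among the 836 called genes at a higher level in replicates 1 and 5, the fold changes of replicates 2, 3 and 4 were set against theirs. The slopes were -0.15, 0.08 and -0.08 (mean -0.0498, SD 0.12), and 32.66%, 54.55% and 35.53% of these genes had the same sign. Glial scores of replicate 2 were 2.625 on the left and 1.871 on the right, and those of replicate 3 were 2.892 and 3.566. Other RNA may have masked a difference in both. In replicate 4, where the slope was -0.08, the scores were closer at 3.324 and 3.162. The other called genes were not in that test. The values are consistent with the libraries of replicates 1 and 5 of a side coming from the same RNA, since the larger of their excess coefficients of variation, 9.52%, lies below that of all other pairs (16.2% or more). In that case the test would compare 1 RNA sample per side, and its p-values would not cover the spread between animals. A difference between the sides in the animals of those libraries stays open and was not tested.

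The spread of the libraries along the first principal component may come from RNA of other cell types carried into the pull-down. Within the 6 libraries of replicates 2 to 4, of 7 relations tested with the astrocyte level, the weakest of 5 other cell type lists was endothelium (Pearson r = 0.763, exact permutation p = 0.0764, adjusted 0.0891; Spearman rho = 0.714, p = 0.136, adjusted 0.159; r = 0.604 without the 2 libraries farthest from the median). Lateral habenular markers were the weakest without those 2 (r = 0.534), with r = 0.953 over all 6 (exact permutation p = 0.00694, adjusted 0.00972; rho = 0.943, p = 0.0167, adjusted 0.0233). Oligodendrocyte markers gave r = 0.988 (exact permutation p = 0.00417, adjusted 0.00729; rho = 0.943, p = 0.0167, adjusted 0.0233; r = 0.829 without those 2) and habenular identity genes r = -0.914 (exact permutation p = 0.00139, adjusted 0.00486; rho = -1, p = 0.00278, the smallest it can give, adjusted 0.00972; r = -0.819). Cholinergic genes gave r = -0.473 (exact permutation p = 0.332, adjusted 0.332; rho = -0.314, p = 0.564, adjusted 0.564; r = -0.463). The fall of the cholinergic level, which this explanation needs, was weak, so the test does not decide on it. CPM levels are shares of a library, so habenular levels fall in part by construction where other RNA takes a larger share. Carried-over RNA and a dissection that took more tissue around the nucleus cannot be told apart, since no input libraries were used here.

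The 90 genes at an unadjusted edgeR p under 0.05, against 812 from chance, may reflect spread from that RNA held in the residual of the fit. With the glial score as a covariate the common biological coefficient of variation was 0.150 (0.1497) in place of 0.446, and 510 genes had an unadjusted p under 0.05. That count is still below chance, so the covariate does not account for the whole shortfall.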
